A study of Mus musculus with 4 samples.

How the data were processed

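Cells of the embryonic mouse lung were measured by single-cell RNA sequencing in 1 sorted E16.5 sample and 3 E17.5 lungs. Per the labels, the E16.5 cells were sorted for an alpha smooth muscle actin reporter and Tbx4-Cre lineage tracing, and the E17.5 cells were live cells of digested lungs after red cell lysis. The extract protocol speaks of sorting into lysis plates, while the cell barcodes and the use of Cell Ranger are those of droplet libraries, so droplets are an inference. The series text names 1 lung at E16.5 and 3 at E17.5. How the E17.5 lungs relate, and whether they come from separate litters, is not stated. Per the submitters' processing notes Cell Ranger 1.3.1 and Seurat 3.0.0 were used, without the role of either being given, and the genome build is not given in the sources used here.

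The deposited signal values are normalized expression on a linear scale, with genes as rows and cells as columns. In each file every cell summed to the same constant, and each cell's values were whole multiples of its smallest value (100% of values, tolerance 0.01). The values are therefore UMI counts multiplied by the sample's median UMI total and divided by the cell's total, and the counts were recovered from them. The files listed 20674 genes, 16449 of them in all 4, and 28 symbols were shared by more than 1 gene ID. The files held 3085, 2682, 2140 and 2657 cells with a median of 3412, 2492, 2648.5 and 2329 genes. No cell had fewer than 1000 UMIs and 32 cells had over 10% mitochondrial UMIs. They were kept, and left out in an alternative. Doublets were called within each sample by simulated doublet scores and removed (31, 37, 33 and 29 cells, or 1.00, 1.38, 1.54 and 1.09%), leaving 3054 cells of the sort and 7380 of the lungs.

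Genes were divided by a seeded hash of their symbol into a clustering group (10292 genes) and a held-out group (10382 genes). All marker genes were placed in the former and all list genes in the latter. Clusters were formed from the former alone and genes were compared only in the latter, so that no tested gene shaped the clusters. The top 10 genes of a cluster, which helped to choose its subclass, were ranked over both groups. The sort and the 3 lungs together were clustered separately with 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1, without batch correction. Clusters were named from marker lists, and names end in "-like" for subclasses since no label gives a cell type. A class score was the mean log2 level of its markers above the average of the E17.5 clusters. Among subclasses with enough markers and score, the one with most markers among the top 10 genes was taken. The score only broke ties, so a name can go against the highest class score. A cluster with more markers of another subclass among its top 10 genes got no subclass, a condition added after seeing the data. Processing used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, umap-learn 0.5.12 and matplotlib 3.10.9.

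For each class and lung with at least 20 cells the mean of per-cell CPM was taken, and log2 of this mean plus 10 was fitted with limma 3.58.1 (R 4.3.3) with the lung as a block and a trend in the prior variance. Genes with a mean of at least 10 CPM were tested, and a Benjamini-Hochberg adjusted p under 0.05 was called. The contractile and matrix classes had 673 and 1066 cells (contractile 1720257, 1662223 and 1463924 UMIs, matrix 3296651, 2741541 and 2434410 UMIs per lung), and the compartments 1862 epithelial, 1368 endothelial, 1938 mesenchymal and 2180 immune cells. Classes of the same lung had correlated deviations (mean correlations of 0.176, 0.166 and 0.255 for contractile and matrix cells, and 0.229, 0.256 and 0.419 for compartments), which the block takes up. The median prior degrees of freedom were 122.2 beside 2 residual ones for contractile and matrix cells, and 18.2 beside 6 for the compartments, so the p-values of the former rest mostly on the spread pooled over genes.

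The tests were tried on simulated data with 200 changed genes. Every gene had the same spread between libraries (0.0759 log2 for contractile and matrix cells, 0.0517 for compartments) beside counting noise. Between contractile and matrix cells 94% of 2-fold and 100% of 4-fold changes were found with 13 false calls of 207, a share above 0.05. For the epithelium 100% of both were found with 4 false calls of 204. Real genes differ in spread and cells vary, which the simulation left out, so it cannot give the error rate on the real data. A count-based test, edgeR 4.0.16 with quasi-likelihood, on sums of recovered UMIs called 1727 genes between contractile and matrix cells, and 3243, 3129, 3246 and 3579 for epithelium, endothelium, mesenchyme and immune cells.

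The E16.5 sort is 1 sample and was not tested. Its mesenchyme (2988 cells, 38397204 UMIs) was compared with the E17.5 contractile class by fold beyond the nearest lung for genes with a mean of at least 50 CPM. The median Poisson half-width of a named gene in the sort was 5.44%. Shares of cells in the sort carry exact binomial 95% intervals. Shares of cells with a UMI are given with each cell thinned to 1000 UMIs.

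The classes, tests, 20 gene lists, alternatives and the rule for naming genes were chosen before the data were examined, except where stated. The rule named 8 genes per direction with the largest change among those called, with the same direction in every lung and a mean of at least 50 CPM, and per list up to 2 called genes per direction. In the stage comparison it named 8 per direction farthest apart and 2 per list and direction. Predicted, Riken, ribosomal and mitochondrial genes were counted but not named, and the results of some genes that the rule would name are not reported. The alternatives were pseudocounts of 1 and 50 CPM, other filters on low values, sums of recovered UMIs, median-of-ratios scaling, no lung block, leaving out each lung, clustering resolutions of 0.5 and 2, a second division of the genes, doublets kept, cells with few UMIs or over 10% mitochondrial UMIs left out, other choices of class, each lung clustered alone, all 4 samples clustered together, and other thinning. The edgeR test and comparisons of matched classes of both stages were chosen after seeing the data.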

Results

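Single-cell RNA sequencing was used to profile cells of the embryonic mouse lung (strain C57BL/6). The E16.5 sample held cells purified by flow cytometry for green fluorescence from an alpha smooth muscle actin reporter together with tdTomato left on by Tbx4-Cre, which tags the descendants of cells that expressed the lung mesenchyme gene Tbx4. The other 3 samples held live cells of E17.5 lungs, named lung 1, lung 2 and lung 3 here. The sort gave 3085 cells and the lungs 2682, 2140 and 2657 cells. The median cell carried 12007 UMIs (unique molecular identifiers, counted molecules) in the sort and 7979, 8493.5 and 7201 in the lungs. The 4 libraries summed to 41038008, 23996253, 20347458 and 21358915 UMIs. The labels do not say whether the lungs came from separate litters or how cells were pooled, so the p-values below cover no more than these 3 samples. limma pooled the spread between samples over genes. Between contractile and matrix cells the median prior degrees of freedom were 122.2 beside 2 residual ones, and for compartments 18.2 beside 6. The very small p-values between contractile and matrix cells thus rest mostly on the pooled spread, not on each gene's own. Levels are means over cells in CPM (UMI counts scaled per cell), with the SD over the 3 lungs.

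Acta2, which encodes alpha smooth muscle actin, and Tbx4 served as the check of the labels. Acta2 averaged 3073 CPM over all cells of the sort and 341 ± 14.5 CPM (n = 3) over all cells of the lungs. An Acta2 UMI was present in 98.3% of sorted cells (median depth 11955.5 UMIs) and in 35.9 ± 4.55% of E17.5 cells. Immune cells of the lungs, which should lack the gene, had one in 18.1 ± 3.90% of cells at median depths of 7754, 7868 and 6764 UMIs. With every cell thinned to 1000 UMIs the shares were 70.5% in the sort, 14.6 ± 0.720% in the lungs and 2.84 ± 0.456% in immune cells. Acta2 averaged 5299 CPM in contractile cells of the sort against 2364 ± 380 CPM in those of the lungs, whereas pericyte-like cells had 1061 and 1145 ± 99.8 CPM. Tbx4 averaged 43.7 CPM in the sort and 12.7 ± 1.81 CPM in all E17.5 cells, but 44.6 and 44.7 ± 5.35 CPM in the mesenchyme of each, against 1.202 ± 0.534 CPM in immune cells. No feature for green fluorescent protein, tdTomato or Cre was listed among the genes, so the reporters themselves could not be read.

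Clusters of the 3 lungs fell into epithelium (25.1 ± 2.07% of cells), endothelium (18.8 ± 3.82%), mesenchyme (26.3 ± 2.42%) and immune cells (29.3 ± 3.27%). Mesothelium made up 0.408 ± 0.313%, with 15, 1 and 16 cells per lung. The epithelium divided into alveolar type 1-like cells (13.2 ± 0.513%), alveolar type 2-like cells (10.4 ± 1.79%), secretory airway-like cells (1.46 ± 0.416%, a cluster that also carried ciliated markers) and 5 neuroendocrine-like cells. The immune cells were mostly macrophage- or monocyte-like (27.6 ± 3.26%), with 1.75 ± 0.120% granulocyte- or mast cell-like. That class included a mixed cluster of 84 cells whose top genes were MHC class II genes (H2-Aa, H2-Ab1, Cd74) beside mast cell and basophil genes (Cma1, Mcpt8). The class score of this cluster was higher for lymphocytes (2.53) than for granulocytes or mast cells (1.76), so its name is uncertain. The mesenchyme divided into matrix fibroblast-like (14.5 ± 1.52%), myofibroblast-like (6.27 ± 0.611%), smooth muscle-like (2.87 ± 0.477%) and pericyte-like cells (2.75 ± 0.673%). The myofibroblast-like cluster had a higher class score for smooth muscle (3.50) than for myofibroblasts (3.25). Its smooth muscle score was also above that of the smooth muscle-like cluster (2.72), so these 2 names rest on top genes and do not part clean cell types. The myofibroblast-like and smooth muscle-like cells together form the contractile class, 9.14 ± 0.469% of E17.5 cells. These shares describe cells recovered after digestion and red cell lysis, not the tissue.

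The sort, clustered alone, was 97.8% mesenchyme (exact binomial 95% interval 97.3 to 98.3, 3054 cells). Myofibroblast-like cells were 35.5% (33.8 to 37.2), pericyte-like cells 34.5% (32.8 to 36.2) and smooth muscle-like cells 12.2% (11.1 to 13.5). The myofibroblast-like clusters again had higher class scores for smooth muscle (3.16, 4.51 and 3.16) than for myofibroblasts (2.33, 2.95 and 2.11). The smooth muscle-like cells included a cluster of 52 of 374 cells whose top genes were cardiac muscle genes (Actc1, Myl7, Nppa, Tnnt2). Matrix fibroblast-like cells were 11.3% (10.2 to 12.5) and adventitial-like fibroblasts 4.32% (3.63 to 5.10), which included a cluster of 24 of 132 cells with the mesothelial genes Upk3b and Wt1 among its top genes beside Dcn and Lum. The contractile class therefore made up 47.7% (45.9 to 49.5) of the sorted cells. A further 38 cells (1.24%) were epithelium, with Sftpc and Scgb3a2 as its first top genes, 21 cells (0.688%) endothelium and 7 erythroid. The epithelial cells had a median of 23070.5 UMIs, against 11955.5 over all sorted cells. Their Acta2 level was 159 CPM, against 23.9 ± 3.55 CPM in E17.5 epithelium. Whether they were single epithelial cells was not tested. No cluster of the sort was named immune. Since cells were named by cluster, scattered immune cells would not have been found, and no upper limit on their share is given. In the epithelial cluster 3 of 9 macrophage or monocyte markers were raised, and immune cells in it were not tested for. Intervals cover counting error only.

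**Figure D1:**
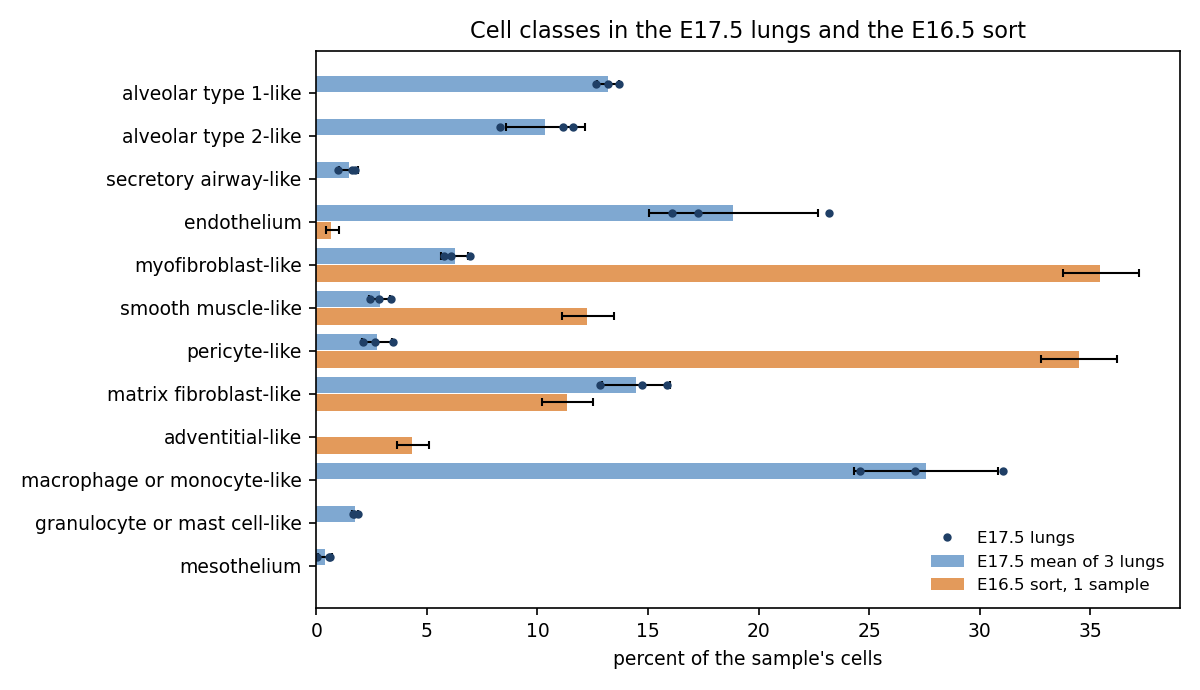
Percent of cells per class; blue bars are means of the 3 E17.5 lungs with SD and points are single lungs, orange bars are the E16.5 sort with its exact binomial 95% interval. Pericyte-like cells are 34.5% of the sort and 2.75% of the lungs, and the epithelial, endothelial and immune classes are nearly confined to the lungs. The 38 epithelial cells of the sort got no narrower name and are not drawn.

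The central comparison asked which genes separate the contractile mesenchyme (673 cells) from the matrix fibroblast-like mesenchyme (1066 cells) within the E17.5 lungs. The genes tested had no part in forming the clusters, although they were ranked among the top genes used in naming them. Map1b, a microtubule-associated protein, had 291 ± 9.24 CPM in contractile and 6.77 ± 0.624 CPM in matrix cells (log2 4.17 ± 0.11 SE, limma adjusted p 2.07e-68, 3 of 3 lungs). Ednrb, an endothelin receptor, reached 800.1 ± 39.7 against 46.3 ± 9.69 CPM (log2 3.86 ± 0.08, limma adjusted p 3.96e-81, 3 of 3 lungs). On the matrix side Adh1, a retinol dehydrogenase, stood at 1037 ± 21.0 CPM against 173 ± 5.80 CPM in contractile cells (log2 −2.52 ± 0.06, limma adjusted p 2.97e-75, 3 of 3 lungs). Figf, which encodes VEGF-D, had 465 ± 13.8 against 75.0 ± 4.53 CPM (log2 −2.48 ± 0.08, limma adjusted p 2.13e-60, 3 of 3 lungs). Every gene named from this comparison had 1 direction in 3 of 3 lungs and passed limma's adjusted threshold of 0.05 unless stated.

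Other leading genes of the contractile side were the Wnt inhibitor Wif1 (log2 3.56), the LIM-domain muscle proteins Pdlim3 (3.54) and Fhl2 (3.17), the signalling gene Net1 (3.49), the growth factor Fgf18 (3.35) and the insulin-like growth factor binding protein Igfbp2 (3.15). From the IGF and imprinted list the growth factor Igf1 (3.08) had 815 against 87.5 CPM. The leading genes of the matrix side were the collagens Col25a1 (−2.68) and Col13a1 (−2.47), the receptor Fgfr3 (−2.60), the transcription factor Maf (−2.58), the actin-binding protein Ablim3 (−2.51) and the lipid droplet coat gene Plin2 (−2.25).

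Of 23 tested cytoskeleton and contraction genes 17 were higher and 4 lower, and 18 and 4 when adjusted over the list alone. Csrp2, a smooth muscle LIM protein, was higher (2.88), whereas the myosin phosphatase inhibitor Ppp1r14a (−1.36) and the integrin Itga8 (−1.09) were lower. Of 16 elastic fibre genes 12 were higher and 1 lower, the same adjusted over the list alone. The latent TGF-beta binding protein Ltbp2 (2.67) and fibulin Fbln2 (1.93) rose. The single lower member, Emilin1, was marginal at −0.18 (limma adjusted p 0.0486, lower in 2 of 3 lungs), and lost its call without lung 2 (−0.15) and without lung 3 (−0.12). Collagen and matrix genes divided, with 11 higher and 7 lower of 21, both over all genes and adjusted over the list alone. Periostin (Postn, 2.45) was higher and fibronectin (Fn1, −1.88, 185 against 705 CPM) lower. Of 12 basement membrane genes 7 were higher, among them the laminin Lama2 (1.33), and only Col18a1 (−1.45) was lower, with the same counts adjusted over the list alone, or 7 and 2 under median-of-ratios scaling.

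Signalling genes also differed by class. Of 20 Wnt pathway genes 11 were higher and 1 lower, the same adjusted over the list alone, or 11 and 2 under median-of-ratios scaling. The Wnt deacylase Notum rose (2.95) while the Wnt enhancer Rspo1 fell (−1.08). Of 8 hedgehog pathway genes 3 were higher and none lower, among them the inhibitor Hhip (2.25), and median-of-ratios scaling called 2 members lower. FGF pathway genes went both ways (5 higher, 6 lower of 15), with the feedback inhibitor Spry1 higher (2.31) and the receptor Fgfr4 lower (−2.26). All 3 tested PDGF pathway genes were higher, including the receptor-like gene Pdgfrl (2.02) and the receptor Pdgfrb (1.77). TGF-beta and BMP pathway genes were 13 higher and 7 lower of 24, or 13 and 8 adjusted over the list alone. The ligand Tgfb3 (1.70) was higher, and the ligands Bmp5 (−1.23) and Bmp3 (−1.17) lower. In the Notch list 5 of 9 genes were higher, led by the target genes Heyl (2.36) and Nrarp (1.64), and Notch2 (−0.84) and Hes1 (−0.45) were lower. Angpt2 (2.43) and the vasoactive receptor Agtr2 (2.94) were higher, and Nrp2 (−1.51) and the prostaglandin receptor Ptger2 (−1.41) lower. The endothelin receptor Ednra was lower (−0.37), opposite to Ednrb. Of 12 vasoactive genes 8 were higher and 2 lower, or 9 and 2 adjusted over the list alone.

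Among IGF and imprinted genes 16 of 19 were higher and 2 lower, the imprinted Mest (−1.02) and the receptor Igf2r (−0.94). Mesenchymal transcription factors were 16 higher and 5 lower of 25, or 18 and 5 adjusted over the list alone. Ebf1 (2.56) and Mef2c (2.28) were higher and the lung patterning genes Hoxa5 (−1.33) and Tbx2 (−0.63) lower. Lipid genes were 5 higher and 4 lower of 15, or 3 and 4 under median-of-ratios scaling, with the fatty acid binding protein Fabp4 higher (2.07) and the triglyceride synthase Dgat2 lower (−1.47). Retinoic acid genes were 2 higher and 2 lower of 7, with the synthetic enzyme Aldh1a1 higher (1.78) and the plasma retinol carrier Rbp4 lower (−0.98). In the hypoxia list 8 were higher and 3 lower of 19, or 6 and 4 under median-of-ratios scaling. Cell cycle genes called were all lower in contractile cells, 16 of 21 in the S phase list and 21 of 21 in the G2 and M phase list, with none higher. Ube2c (−1.46) and Top2a (−1.32), which act in mitosis, showed the largest falls. The matrix class held a cluster of 121 cells with the cell cycle genes Spc25 and Hist1h2ap among its top genes, beside Wnt2 and Adh1. No contractile cluster of the lungs had such top genes. Whether cycling cells of other mesenchyme were placed in that cluster was not tested, so these counts may depend on how the classes were formed. Immediate early and stress genes went both ways (7 higher, 9 lower of 19, or 5 and 10 under median-of-ratios scaling), with the transcription factor Atf3 higher (1.44) and the phosphatase Dusp1 lower (−0.50). Adjusted over the list alone, the hypoxia list gave 9 higher and 3 lower and the immediate early list 8 and 9, and the other lists given without such a count were unchanged.

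The contractile values average over myofibroblast-like and smooth muscle-like cells, which were far apart for several of these genes. Myofibroblast-like cells held most of the Ednrb (1153 against 31.3 CPM in smooth muscle-like cells), Hhip (655 against 15.6), Igf1 (1119 against 166), Fgf18 (195 against 22.04) and the stress gene Hspb1 (1297 against 151). Smooth muscle-like cells held more of the semaphorin receptor Nrp1 (648 against 158 CPM), Fn1 (492 against 44.0), Fabp5 (287 against 41.4) and Fabp4 (116 against 1.41). An Agtr2 level of 282 CPM in smooth muscle-like cells compared with no UMI in myofibroblast-like cells. The smooth muscle-like cluster also carried adventitial markers, and its top genes Agtr2, Penk and Dpep1 were top genes of an adventitial-like cluster of the sort, so adventitial cells in it are not excluded. An Acta2 UMI was present in 56.0 ± 0.515% of its cells thinned to 1000 UMIs (80.8% unthinned), against 74.2 ± 4.69% (97.1%) of myofibroblast-like and 34.8 ± 1.81% (77.1%) of matrix cells. Ednrb, Hhip and Hspb1 were lower than in matrix cells when smooth muscle-like cells stood alone for the class, and Fabp5 was lower (−0.57) and Nrp1 near the matrix level (−0.03) when myofibroblast-like cells did. Elastin (Eln), a clear gene of both, had 10201 ± 1524 CPM in myofibroblast-like and 13829 ± 514 CPM in smooth muscle-like cells, 2977 ± 207 CPM in matrix cells and 493 ± 351 CPM in pericyte-like cells. No test between these subclasses was run.

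Of 4057 genes tested between contractile and matrix cells, limma called 1180 higher and 638 lower, of which 257 and 117 differed at least 2-fold. The share of calls that were higher was 64.9%, and 50.3% (902 higher, 891 lower) under median-of-ratios scaling, which moved the median of all genes from 0.09 to −0.01. A count-based test (edgeR) on recovered UMIs called 869 higher and 858 lower of 4052. The split between higher and lower calls therefore depended on the scaling, while no gene named from this comparison turned under median-of-ratios scaling.

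**Figure D2:**
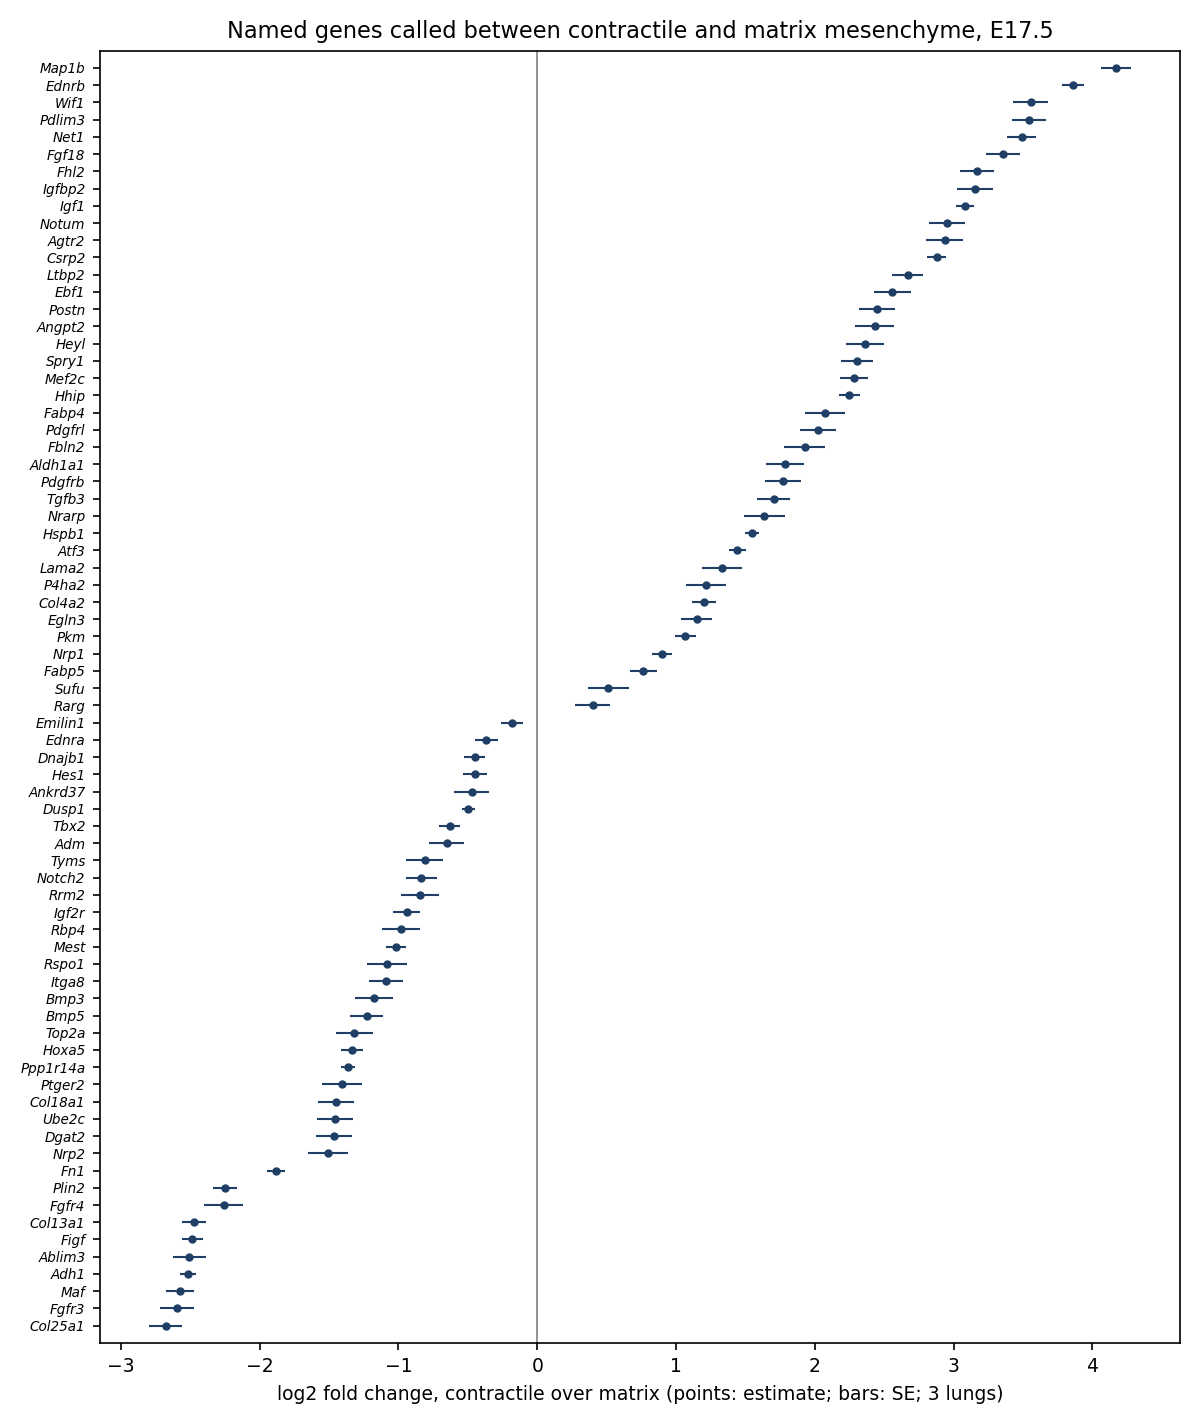
Log2 fold change of genes named by the rule that passed, contractile over matrix mesenchyme in the 3 E17.5 lungs; points are limma estimates and bars their SE. Values run from −2.68 for Col25a1 to 4.17 for Map1b.

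The mesenchyme of the E16.5 sort, which mixes contractile with other classes, was set against the E17.5 contractile class. No test was made, since there is 1 sorted sample and stage, reporter, sort and library all change together. Only values are given. A gene counts as apart when its level in the mesenchyme of the sort was at least 2-fold above the highest or below the lowest lung. Of 1486 genes with a mean of at least 50 CPM, 26 were higher and 99 lower in the sort. The counts were 6 and 77 with only the contractile cells of the sort. They were 3 and 76 when, in addition, the 4 samples were clustered together. Each lung set against the other two in the same way gave 1 higher and 0 lower, 1 and 0, and 2 and 6. The transcription factor Atf3 had 11.1 CPM in the sort and 658 ± 42.3 CPM in the lungs (log2 −4.98). Klf4, another stress-responsive factor, had 19.1 against 885 ± 84.7 CPM (−4.94). On the other side the membrane protein Itm2a had 660 against 120 ± 22.9 CPM (2.39, or 0.37 and not apart in contractile cells alone) and the tubulin regulator Stmn1 882 against 213 ± 34.2 CPM (2.01). The smallest UMI sum behind a named gene in the sort was 156, and the widest Poisson interval was ±16.03%.

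Immediate early and stress genes made up 17 of the 99 lower genes. Their median log2 difference was −2.23 over 19 members, and none was higher. Fosb had 25.3 against 751 CPM and Ier3 34.2 against 400 CPM. Outside the list, the shear-responsive factor Klf2 (73.2 against 1216 CPM) and the kinase regulator Trib1 (10.9 against 190) were also lower. With only smooth muscle-like and myofibroblast-like cells of the sort the median was −1.81, with 16 lower and 1 higher. Elastic fibre genes had a median of −0.84 over 14 members, 5 of them apart and lower. In contractile cells alone this was −0.55 with 2 lower, in myofibroblast-like cells of both stages −0.37 with 1, and in matrix cells of both −0.08 with none. Eln had 2097 CPM in the sort and 11301 ± 1364 CPM in the lungs (−2.42), and Ltbp2 39.5 against 149 ± 3.39 CPM (−1.69). In contractile cells alone Eln stayed apart (−1.79) and Ltbp2 did not (−1.03). The matrix glycoprotein Tnc (−1.53), the Wnt regulators Notum (−1.61) and Dkk3 (−1.38), the growth factor Fgf7 (−1.36) and the TGF-beta co-receptor Tgfbr3 (−1.44) were apart in the whole mesenchyme. In contractile cells alone their log2 values were −0.99, −1.01, −1.02, −0.96 and −0.90, less than 2-fold below the lowest lung. The FGF inhibitor Spry2 (−1.45), Igfbp2 (−2.59), Agtr2 (−1.95) and the hypoxia gene Bnip3 (−1.40) were apart in both. Agtr2 was a top gene of the smooth muscle-like cluster of the lungs but, in the sort, of an adventitial-like cluster left out of the contractile class. Ctsh, a protease abundant in epithelium (2369 CPM), was lower as well (−2.88), but after free RNA was subtracted from the lungs the levels were 4.12 CPM in the sort and 4.81 CPM in the lungs.

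Of the 32 members of the G2 and M phase list 6 reached a mean of 50 CPM over the sort and the lungs. Ube2c, Cenpa and Birc5 did so only through the sort, with under 50 CPM in every lung. Their direction was thus fixed by the filter. Of the 6 members 5 were apart and higher, with a median of 1.84. In contractile cells alone the median was 0.86 over 4 members with 1 apart, in pericyte-like cells of both stages 0.73 with none apart, and in matrix cells of both 1.17 with 4 apart. Ube2c (173 against 24.6 CPM), the centromere histone Cenpa (185 against 33.7), the mitosis gene Birc5 (137 against 23.3) and, outside the list, the histone Hist1h2ap (313 against 59.2) and the tubulin Tuba1b (1004 against 327) were apart. Pdgfrb (207 against 69.1 CPM), Ebf1 (358 against 73.6), Mest (698 against 197), the imprinted Dlk1 (1682 against 709), the phosphodiesterase Pde5a (188 against 64.6) and the guanylate cyclase Gucy1b3 (186 against 74.9) were also higher. In contractile cells of the sort alone these 6 were no longer apart, at 0.17, 0.38, −0.05, 0.04, 0.58 and 0.32. Hist1h2ap (1.58) and Tuba1b (1.06) were not apart there either, and Stmn1 (1.71) and Cenpa (1.88) stayed apart. Ube2c (1.96) and Birc5 (1.62) were also still 2-fold above the highest lung, but under the filter of a 50 CPM mean. The cytoskeleton and contraction list had a median of 0.02 over 21 members with none apart, or −0.02 under median-of-ratios scaling and 0.26 in contractile cells alone.

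**Figure D3:**
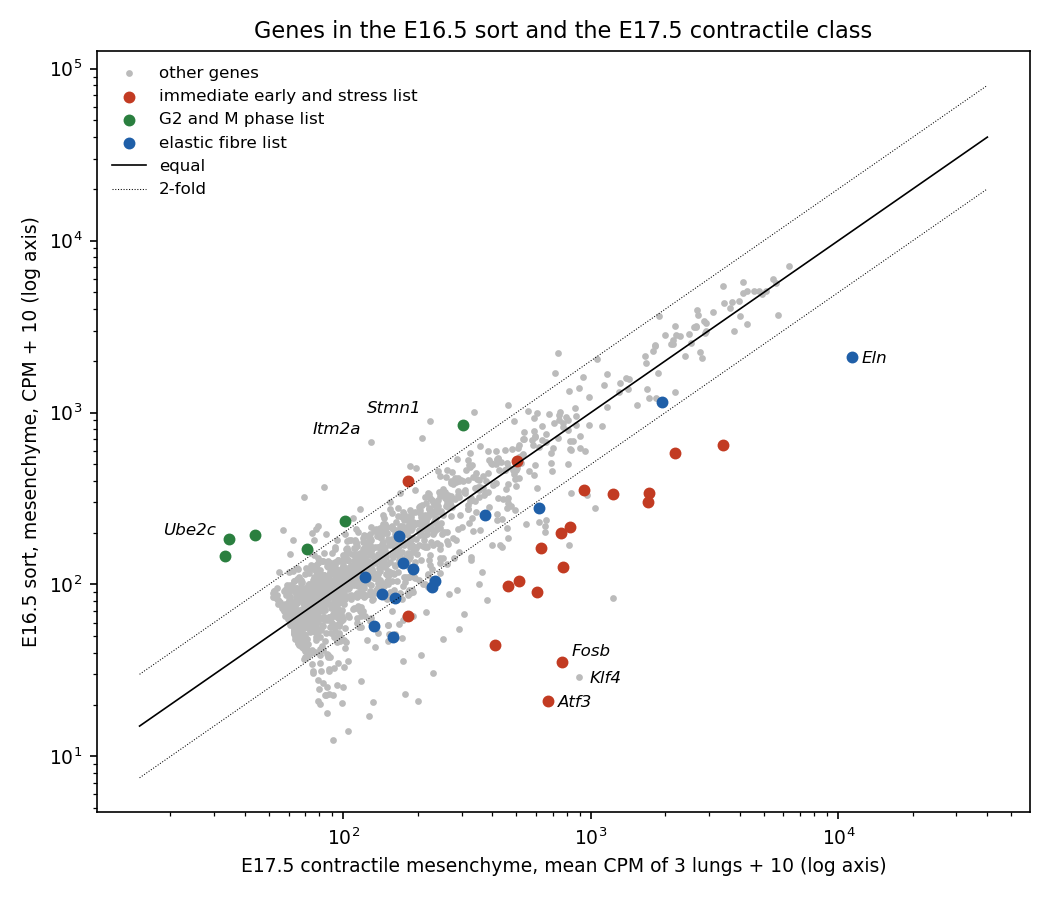
Each point is a gene, with its mean CPM + 10 in the E17.5 contractile class of 3 lungs on the horizontal log axis and its CPM + 10 in the mesenchyme of the E16.5 sort on the vertical log axis; the solid line marks equality and dotted lines 2-fold. Most of the immediate early list lies below the line (median log2 −2.23). The 6 members of the G2 and M phase list that passed the filter, a mean that includes the sort, have a median of 1.84.

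Cells carrying a Mki67 or Top2a UMI, both transcripts of dividing cells, were counted after thinning each cell to 1000 UMIs. They made up 11.01% (9.91 to 12.2) of the mesenchyme of the sort and 4.55 ± 1.73% (n = 3) of the mesenchyme of the lungs. In the contractile class the shares were 6.52% (5.31 to 7.91) and 2.93 ± 1.47%, a ratio of 2.23. Myofibroblast-like cells had 7.39% and 2.76 ± 1.68%, and smooth muscle-like cells 4.01% and 3.28 ± 1.49%, a difference within the spread between lungs. Pericyte-like cells had 16.52% against 7.38 ± 5.58%, and matrix fibroblast-like cells 17.1% against 5.06 ± 2.06%. The ratio was 3.37 for matrix cells but 2.12 unthinned, and 2.67 for myofibroblast-like cells but 4.09 by mean CPM of the G2 and M phase list. In the mesenchyme of the lungs the only cluster with cell cycle top genes was matrix fibroblast-like (121 cells). The sort also had pericyte-like and myofibroblast-like ones. Shares by class may therefore depend on how the clusters were formed. Of 132 adventitial-like cells in the sort 1 carried such a UMI (0.758%). Among other E17.5 cells the share was 12.0 ± 1.29% in endothelium, 11.7 ± 1.08% in immune cells and 4.19 ± 0.903% in epithelium. Unthinned shares in the contractile class were 26.2% at a median depth of 11288 UMIs in the sort, and 12.1 ± 5.37% at 6693.5, 7966 and 6390.5 UMIs in the lungs. No cell type lacks both transcripts for certain, so no background share from free RNA is given.

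**Figure D4:**
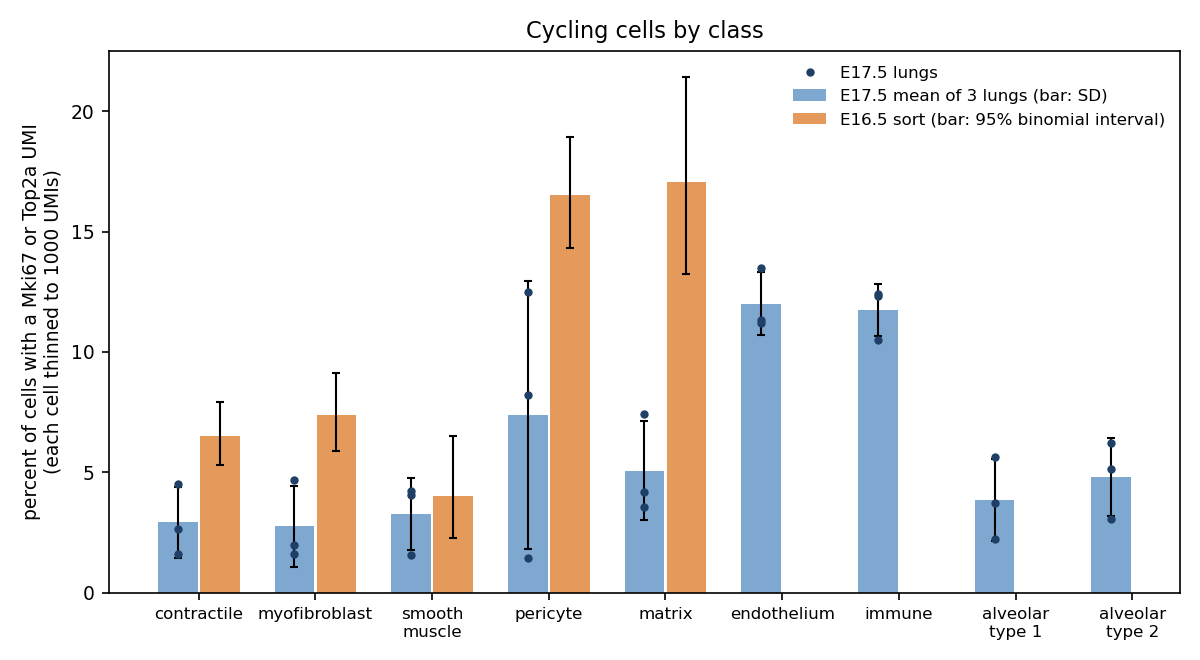
Percent of cells with a Mki67 or Top2a UMI after thinning to 1000 UMIs, by class; blue bars are E17.5 means with SD, points single lungs, and orange bars the E16.5 sort with exact binomial 95% intervals. The sort is above all 3 lungs in matrix, pericyte-like and myofibroblast-like cells, and within their range in smooth muscle-like cells (4.01%).

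Each compartment of the E17.5 lungs was then compared with the mean of the other 3, to describe which signalling, matrix and metabolic genes each carries. Every gene named had 1 direction in 3 of 3 lungs and passed limma's adjusted threshold, and the counts of the lists named here were the same adjusted over the list alone. In the epithelium the surfactant-associated Sfta2 had 1706 ± 26.6 CPM against at most 36.2 ± 5.58 CPM elsewhere (log2 5.29 ± 0.06 SE, limma adjusted p 4.47e-28, 3 of 3 lungs). The tight junction genes Cldn18 (5.24) and Cldn3 (4.66) followed. The matrix, vessel and mesenchyme genes Igfbp4 (−3.34), Mef2c (−3.32), Klf2 (−3.06) and Zeb2 (−3.01) were lowest. The ligands Shh (3.17, 96.4 against at most 2.43 CPM), Pdgfa (3.12), Tgfb2 (2.53) and Vegfa (1.96) and the FGF response genes Etv5 (3.22) and Fgfr2 (2.44) were higher. Among lipid genes 12 of 19 were higher and 6 lower, with the surfactant phospholipid enzyme Lpcat1 (3.56) and the desaturase Scd1 (3.004) at the top and Plin2 (−1.34) lower. The imprinted Dlk1 (3.97) and Meg3 (3.78) were higher as well. Basement membrane genes were 10 higher and 6 lower of 16, with collagen Col4a4 (2.60) higher and Nid1 (−2.10) lower. All 26 S phase genes were lower, Mcm3 (−1.55) most. Of 4215 genes 1154 were higher and 2082 lower, or 1448 and 1767 under median-of-ratios scaling (35.7% and 45.0% of calls higher, median of all genes −0.13 and −0.05) and 1542 and 1701 by edgeR.

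In the endothelium the sodium channel Scn7a had 798 ± 11.1 CPM against at most 21.8 ± 5.56 CPM elsewhere (log2 5.13 ± 0.08 SE, limma adjusted p 7.38e-26, 3 of 3 lungs). The vessel genes Plvap (4.85), Gpihbp1 (4.79), Sox17 (4.68) and Aplnr (4.62) followed, with Mest at 3606 ± 112 CPM (4.68). The RNA-binding Celf2 (−3.22), Meg3 (−3.002) and Cebpa (−2.52) were lowest. VEGF and angiopoietin genes were 8 higher and 4 lower of 12, and Notch genes also 8 and 4 of 12. Hey1 (3.45), the Notch-modifying Mfng (3.35), Pdgfb (2.73), the BMP receptor Acvrl1 (3.53), collagen Col4a1 (2.81), the fatty acid transporter Cd36 (2.80) and the angiotensin-converting enzyme Ace (3.67) were higher. All 26 S phase genes were higher, Mcm5 (1.55) most. The hypoxia list turned on the scaling, with 8 higher and 3 lower of 20 against 6 and 11 under median-of-ratios scaling, although Epas1 (2.82) was higher under both. Lrp6 (0.30) and Ier3 (0.38) passed here but not under median-of-ratios scaling (0.09 for each). Calls were 2176 higher and 1176 lower, or 1400 and 1775 under median-of-ratios scaling (64.9% and 44.1% higher, median of all genes 0.16 and −0.05) and 1556 and 1573 by edgeR.

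In the mesenchyme as a whole Eln led, with 5619 ± 588 CPM against at most 490.4 ± 74.3 CPM elsewhere (log2 4.91 ± 0.05 SE, limma adjusted p 2.98e-29, 3 of 3 lungs). The proteoglycan Bgn (4.53), collagen Col6a2 (4.53) and the elastin crosslinking enzyme Lox (4.51) followed, and all 21 collagen and matrix genes were higher. Elastic fibre genes were 16 higher and 1 lower of 17, the lower one Emilin2 (−1.07). The tetraspanin Cd9 (−3.28), the junction gene F11r (−2.88) and the mitochondrial Ucp2 (−2.88) were lowest. Signals and receptors higher in mesenchyme were Figf (4.25), Hhip (4.11), Wnt5a (3.14), Pdgfrb (3.04), Fgf7 (2.82) and Ednra (3.73), with the transcription factors Tbx2 (3.67) and Tbx5 (3.52). Immediate early and stress genes were 16 higher of 19 with none lower, or 15 and 2 under median-of-ratios scaling. Cell cycle genes were mostly lower (18 of 26 in S phase, 28 of 29 in G2 and M phase), as were the glycolytic Gapdh and Pkm (−1.29 each). Calls were 1795 higher and 1456 lower, or 1446 and 1769 under median-of-ratios scaling (55.2% and 45.0% higher, median of all genes 0.06 and −0.05) and 1553 and 1693 by edgeR.

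In immune cells the protease Ctss had 755 ± 29.3 CPM against at most 16.54 ± 1.80 CPM elsewhere (log2 4.94 ± 0.06 SE, limma adjusted p 1.03e-28, 3 of 3 lungs). The chemokines Cxcl2 (4.80), Ccl4 (4.38) and Ccl3 (4.34), the leukotriene gene Alox5ap (4.74) and the myeloid factor Spi1 (4.67) were also high. Fstl1 (−4.37), Sparc (−4.20) and the collagen chaperone Serpinh1 (−3.99), all secretory matrix genes, were lowest. No member of the basement membrane (16 lower of 16), FGF (14 of 14) or IGF and imprinted lists (19 of 19) was higher. Matrix genes higher than the mean of the others included Emilin2 (3.59) and Fn1 (2.27), although Fn1 had 434 CPM in immune cells and 460 CPM in mesenchyme. Lipoprotein lipase Lpl (3.32), Pparg (2.18), Tgfb1 (1.77) and the glycolytic Gapdh (1.15) were higher. S phase genes were 12 higher and 7 lower of 26, or 19 and 4 under median-of-ratios scaling. Calls were 1215 higher and 2447 lower, or 1699 and 1881 under median-of-ratios scaling (33.2% and 47.5% higher, median of all genes −0.28 and −0.05) and 1681 and 1898 by edgeR.

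**Figure D5:**
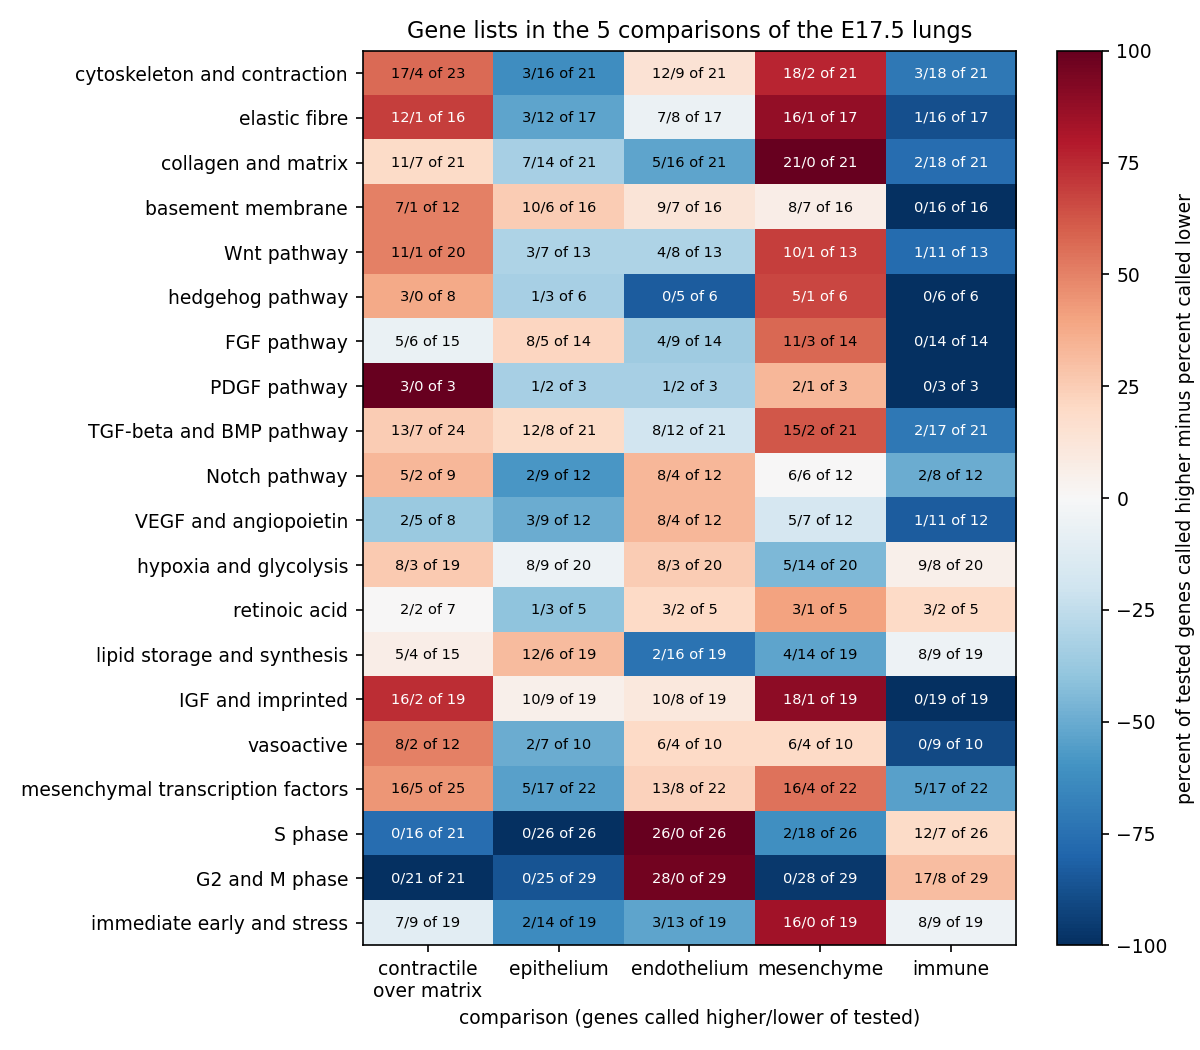
Rows are the 20 gene lists and columns the 5 comparisons of the E17.5 lungs; each cell gives genes called higher and lower of those tested, and colour the percent higher minus the percent lower. The collagen and matrix list is 21 of 21 higher in mesenchyme and 18 of 21 lower in immune cells.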

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

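All tests of explanations in this part were chosen after the result was seen. The contrast of contractile and matrix cells, computed within the E16.5 sort, ran opposite to every E17.5 lung for 6 of the 75 named genes that had 1 direction in all lungs. The log2 values in the sort and the lungs were −0.65 and 3.15 for Igfbp2, 0.13 and −0.45 for Hes1, 0.41 and −1.51 for Nrp2, 0.0791 and −0.65 for Adm, −1.74 and 2.94 for Agtr2, and 0.15 and −0.45 for Dnajb1. Agtr2, an angiotensin receptor, had 4.09 CPM in contractile and 37.0 CPM in matrix cells of the sort. It was a top gene of the smooth muscle-like cluster of the lungs and of an adventitial-like cluster of the sort, which entered neither class. These differences were not tested. A further 2.16% of the sort's cells lay in clusters outside the mesenchyme, which the stage comparison left out. The values of Acta2, Tbx4 and sex-linked transcripts over all sorted cells include them.

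Immediate early and stress genes were lower in the sort than in the E17.5 contractile class. Free RNA in the E17.5 libraries is argued against, since 17 of the 17 lower list genes were still apart after each lung's free RNA was subtracted. Cell handling during dissociation or sorting cannot be told apart from stage or sort: 12 of the 17 genes were below every compartment of every lung, and the sort is the only sample of its stage and protocol. A difference between stages stays open as untested. Handling may therefore account for some or all of the pattern.

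Of the genes higher in the mesenchyme of the sort than in the E17.5 contractile class, tested for cells other than contractile mesenchyme in the sort, 7 of 26 were still 2-fold apart in contractile cells alone. For more cycling cells in the sort, 10 of 26 were still 2-fold apart after cells with Mki67 or Top2a were left out. With both restrictions 2 remained by this measure, but 19 of 26 were above every lung, with a median log2 of 0.55 (1.49 before). Cenpa had 1.25 ± 0.28 (SD over lungs, 2.19 ± 0.39 before) and Hmgb3 1.27 ± 0.31 (1.46 ± 0.29 before), no longer 2-fold above the highest lung. Cells were left out on unthinned UMIs, 26.2% of contractile cells in the sort and 12.1% in the lungs. The sort was deeper, so its cycling cells may have been removed more fully. Several of the 26, such as Ube2c, Birc5 and Cenpa, are cell cycle genes whose fall was built in. The counts therefore cannot measure how much cycling accounts for. Non-contractile and cycling cells of the sort may account for part of this side. Matrix cells of both stages had 24 genes higher, 6 of them among the 26, with Dlk1 (2.55) 1 of these. They differed in cycling as well, with 17.1% in the sort and 5.06% in the lungs, and 4 G2 and M phase and 2 S phase genes were among the 24. A difference between stages stays open as untested.

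Xist and Y-linked transcripts lay in different cells of each sample. Free RNA alone is argued against, since the share of cells with a Y-linked UMI was at least 7.21 times higher in cells without Xist than in cells with it. Cells with both numbered at most 0.363 of those given by independence, in line with cells of both sexes in each sample. No biological explanation was tested beyond this. The series text names 1 lung for the sort, and pooling of embryos may explain both sexes.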

How the results depend on the processing

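The edgeR test and the comparisons of pericyte-like, matrix, myofibroblast-like and smooth muscle-like cells of both stages were chosen after the result was seen, as was the count of splits. Of 398 named genes of the tested comparisons, with a gene counted once for each comparison that named it, 371 kept their direction and call in every alternative run. Of 6344 recomputed values 6298 were the same, 34 lost their call, 12 turned and none gained one. Except where a construction is named, the cause was not tested.

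With at least 50 CPM fewer genes were tested, and calls fell from 1818 to 845 (contractile and matrix), 3236 to 1161 (epithelium), 3352 to 1194 (endothelium), 3251 to 1165 (mesenchyme) and 3662 to 1256 (immune cells). With no filter more were tested, giving 5269, 5260, 5323 and 6152 for the 4 compartments. Smooth muscle-like cells alone gave 1152 calls against matrix cells, and turned Ednrb (−0.59), Hhip (−1.96), Hspb1 (−1.02), Itga8 (0.17), Hes1 (0.0364), Ankrd37 (0.0418) and Mest (0.00536). Myofibroblast-like cells alone turned Nrp1 (−0.0337) and Fabp5 (−0.57). In the mesenchyme a pseudocount of 1 CPM turned Fzd4 (0.065) and 50 CPM turned Pdgfa (−0.0293), and in immune cells 50 CPM turned Mef2c (−0.0786).

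Immune cells were 24.3% of E17.5 cells at resolution 0.5 and 25.7% with doublets kept, and contractile cells 7.95% with each lung clustered alone, which left a cluster of lung 2 without a subclass. In the sort, mesenchyme was 96.9% at resolution 2, and matrix cells 13.7% at resolution 0.5, 14.997% with the second gene split and 12.6% with doublets kept. Contractile cells were 49.8% at resolution 0.5. Sums of recovered UMIs gave Acta2 2898 CPM in the sort and 306 CPM in the lungs, and Tbx4 41.1 CPM in the sort.

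The stage comparison had 125 genes apart. The count was 69 with a pseudocount of 50 CPM and 226 at a mean of at least 10 CPM (more genes compared). With only smooth muscle-like and myofibroblast-like cells of the sort it was 83 (Mest turned, −0.0469). It was 79 with the 4 samples clustered together, a setting that also took only those cells of the sort. Pericyte-like cells of both stages gave 56 and smooth muscle-like cells of both stages 83. Matrix cells kept Itm2a (1.59) apart. Pericyte-like cells turned Itm2a (−0.29), Pdgfrb (−0.15), Mest (−0.39), Pde5a (−0.15) and Gucy1b3 (−1.05), and smooth muscle-like cells Hist1h2ap (−0.56) and Mest (−0.14).

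Leaving out 1 lung ended the call of Ankrd37 (−0.37 without lung 1), Emilin1 (−0.15 without lung 2, −0.12 without lung 3) and Sufu (0.34 without lung 2) between contractile and matrix cells. It also ended those of Notch2 in epithelium (0.16 without lung 1, 0.19 without lung 2), Rxra (−0.17 without lung 1) and Slc2a1 (−0.14 without lung 2) in endothelium. Alternatives with nothing to change were adding adventitial-like cells to the E17.5 matrix class, since no such cluster was found there, and removing cells under 1000 UMIs, of which there were 0. Classes with few cells, such as the 1 mesothelial cell of lung 2, were too shallow to test.

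Of the 100 splits of the libraries counted per compartment, 1 (the real one) called as many genes. For epithelium 3236 genes compared with at most 1519 in another split, and for endothelium 3352 with 1518. For mesenchyme 3251 compared with 594, and for immune cells 3662 with 721. Of 64 splits that took 1 class from each lung, as the real one does, 4, 2, 3 and 1 called as many, the real one included. Those that mixed compartments gave at most 1162, 1369, 1369 and 922, so the others that called as many were the remaining compartments. The compartments were themselves defined from expression, so the real split was bound to stand out. These counts therefore cannot decide on chance. Between contractile and matrix cells the 10 splits, 4 of them within lungs, are too few for a share under 0.05 (real value 1818, highest other 0).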

Other observations

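The tests of explanations cited in this part were chosen after the result was seen, and so were the genes named here. Across the 10 larger classes of the E17.5 lungs, lists differed in where their genes were highest. Of 16 lipid genes 8 were highest in alveolar type 2-like cells, among them Fabp5 (1436 ± 247 CPM), Lpcat1 (949 ± 47.3 CPM), Scd1 (246 ± 74.1 CPM) and Fasn (153 ± 27.6 CPM). The imprinted Dlk1 reached 5862 ± 511 CPM there. In alveolar type 1-like cells Vegfa (157 CPM) and Pdgfa (257 CPM) were highest. Of 13 vasoactive genes 6 were highest in pericyte-like cells, which also held Gucy1b3 (779 ± 62.7 CPM), Pde5a (408 ± 28.5 CPM), Kcnj8 (278 ± 46.8 CPM) and Agtr1a (206 ± 18.8 CPM). Of 11 Wnt genes 6 were highest in myofibroblast-like cells, and of 12 elastic fibre genes 7 in smooth muscle-like cells. Of 11 S phase genes 10 were highest in endothelium.

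In 3 matched comparisons of the sort with the lungs (contractile, pericyte-like and matrix cells), 36 of 1130 genes measured in all were apart and lower in the sort in every class, and none was higher. Of these 36, 16 were immediate early genes and 8 predicted genes or ribosomal protein genes and pseudogenes. The ribosomal pseudogene Rpl10-ps3 had 169.97 CPM in contractile cells of the sort and 803 ± 315 CPM in those of the lungs, and Rpl6l 259 against 1031 ± 118 CPM. The cause was not tested.

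The surfactant gene Sftpc, a product of alveolar type 2 cells, was also read in endothelium, mesenchyme and immune cells at E17.5, at 2205 CPM in immune cells of lung 1. Subtracting free RNA from the lungs, at a mean of 12.1% (10.99 to 13.1%) of the average profile, left 84 of the 99 lower genes of the stage comparison apart. All 26 higher genes stayed apart too, but this was fixed in advance, since the subtraction could only lower the levels of the lungs.

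Y-linked UMIs were present in 74.5% of cells without Xist in the sort (median 12118.5 UMIs) and 54.1, 57.4 and 47.8% in the lungs. In cells with Xist they were present in 5.12% of the sort (median 11929 UMIs) and in 7.26, 7.91 and 6.63% of the lungs. Of 3054 sorted cells 2580 carried Xist.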
